A study of Helianthus annuus with 6 samples.

How the data were processed

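Gene expression was measured by RNA sequencing in petioles of cultivated sunflower (Helianthus annuus). Per the labels' protocols, poly(A) RNA was enriched from total RNA with oligo(dT) beads, fragmented, copied into double-stranded cDNA, ligated to adapters, size-selected and amplified by PCR. The libraries are of bulk tissue: although a library field in the labels names single cells, each file holds 1 value per locus. There were 6 libraries, 3 from the leaf-flat inbred line 19G and 3 from the leaf-compact inbred line 20G. Groups and replicate numbers were taken from the sample titles. No label says whether the 3 libraries of a line came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

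The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, as the labels name the unit of the authors' columns. The aligner, the transcript assembler, the genome build and any filter are not given in the sources used here. Each file lists the same 70842 loci. Of these, 57126 carry RefSeq LOC identifiers and 13716 carry identifiers of the authors' own new loci. All 57126 RefSeq identifiers matched a RefSeq gene table of the sunflower assembly HanXRQr2.0-SUNRISE, and they were the same 57126 genes as its protein-coding LOC entries. Because neither the labels nor the files name a build, that table was used only for gene symbols and for which genes neighbour each other, and no coordinates are given. The new loci have no entry in it, so their positions are not analysed here.

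FPKM carries no read counts, and the sequencing depth is unknown. The low values were examined for a common step that would recover whole reads. Among loci under 0.1 FPKM in both libraries of a pair, the fullest bin of the log2 ratio (width 0.01) held between 0.9% and 2.1% of loci. The share expected without a step was not computed, so a step is not excluded. None was recovered, and no count-based test was run. No counting interval or detection limit can be given, and a locus without signal is described as listed at 0. The gene lists fixed before the data were examined, 22 in number and covering hormones, organ angle, cell walls, cell type markers, the clock and stress, were patterns on gene product names. Neither the files nor the gene table pair the identifiers with products, so none of these lists has a result, and the clock, handling and tissue marker checks they held were not made.

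Loci with FPKM of at least 1 in 3 or more of the 6 libraries were tested, 28292 in all. Values were transformed to log2(FPKM + 1), which understates the change of low loci. The lines were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 6 libraries in one fit without covariates. The test was two-sided with Benjamini-Hochberg adjustment. A locus was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size, and differences are 20G minus 19G. In simulated libraries with the real means and spreads of these 28292 loci and 200 changed loci in each of 5 draws, the fit called 41.7% of loci with a log2 change of 1.5, 66.7% with a change of 2 and 86.2% with a change of 3. It called 0.0% of loci with a change of 1, where the fold criterion and the adjusted p both act. False calls averaged 9.6 per draw at most. The 200 changed loci were far fewer than the 4849 called in the real fit. Under Benjamini-Hochberg adjustment, the share of changed loci called and the number of false calls depend on how many loci change. These figures therefore do not carry over to the real fit.

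Genes named in the text follow a rule fixed before the data were examined: the 6 largest increases and the 6 largest decreases among called genes with a mean FPKM of at least 5 whose 3 values in one line all lie above the 3 in the other. The rule also required a product name and listed members of product-based gene families. Those parts could not be applied, and the rule was therefore used on RefSeq genes only, without the product clause. Genes named outside it are said to have been chosen after their values were seen.

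Loci listed in only one line were defined, after the data had been seen, as FPKM of at least 1 in all 3 libraries of that line and 0 in all 3 of the other. Neighbours were assessed, also after the data had been seen, over 23108 tested RefSeq genes placed in order on the chromosomes of the table. Pairs of called genes at a given distance were counted and compared with calls permuted 10000 times among genes of like mean expression, in 10 bins of equal size (one-sided, Python 3.11.15, NumPy 2.4.6). The count was tested on simulated calls, where random calls gave a ratio of 0.99 and planted blocks a ratio of 2.31. New loci were compared with RefSeq genes in 20 bins of mean expression, with 10000 permutations.

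The alternatives tried were another pseudocount, no filter and a stricter filter, quantile and median-of-ratios scaling, limma without the trend and with sample weights, other calling thresholds, the replicate number as a block, and each library left out in turn. Whether the replicate numbers pair the libraries was checked, and the values are given with the alternatives.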

Results

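Petiole transcriptomes were compared between 2 sunflower inbred lines that differ in how steeply the leaf stalk is held: 19G, whose leaves are held flat with a large petiole inclination angle, and 20G, whose leaves are compact with a small angle. Each line was represented by 3 libraries. Leaf form and line coincide in this design, so no difference in expression can be tied to the petiole angle apart from other differences between the lines. Sequencing depth is unknown because the deposited unit is FPKM. The FPKM values summed to between 638235 and 701884 per library. Between 26075 and 27468 loci reached 1 FPKM in a library, of which 21803 to 22759 were RefSeq genes and 4133 to 4713 were new loci assembled by the authors.

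The libraries separated by line. The first principal component of the tested loci held 71.0% of the variance and placed the 19G libraries at -103.4 to -74.0 and the 20G libraries at 91.4 to 95.2. Across the tested loci, which are not independent replicates, Pearson's r was 0.951 to 0.974 between the 20G libraries and 0.746 to 0.796 between lines. Within 19G, replicates 2 and 3 correlated at 0.972, while replicate 1 correlated with them at 0.906 and 0.886. The second component, with 16.7% of the variance, set 19G replicate 1 at 93.1, 19G replicates 2 and 3 at -31.2 and -48.3, and the 20G libraries in between. In 19G replicate 1, 4278 loci lay over 2-fold from the mean of the other 2 libraries of its line, against 594 to 1984 loci in the other libraries. In each pair of libraries, 0 of the 33165 to 36882 loci above 0 in both had exactly equal deposited values.

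**Figure D1:**
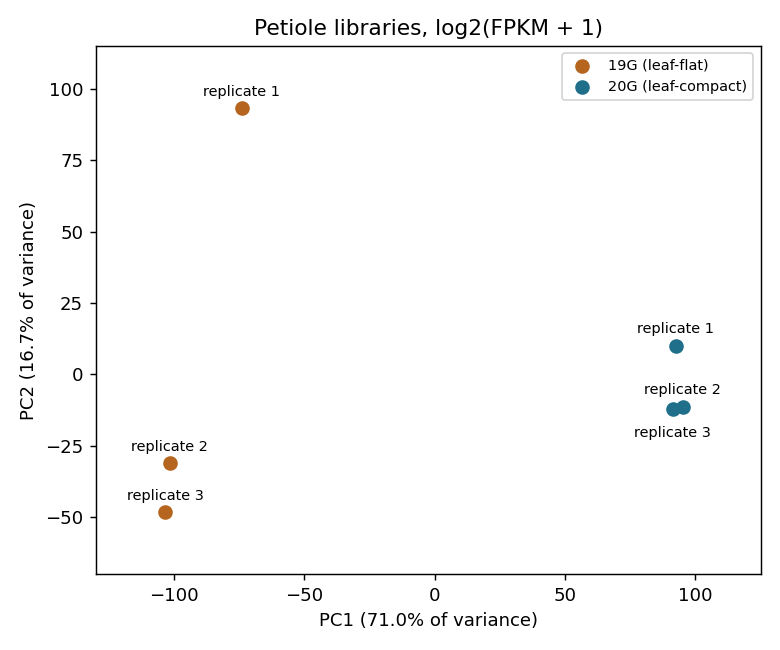
Principal components of log2(FPKM + 1) over the 28292 tested loci, with 1 point per library, coloured by line. PC1 (71.0% of variance) separates the lines and PC2 (16.7%) sets 19G replicate 1, at 93.1, apart from the other 5 libraries.

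Which genes the petioles of the 2 lines express differently was asked by comparing 20G with 19G. Of 28292 tested loci, 4849 (17.1%) were called, with 2388 higher and 2461 lower in 20G (limma, Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1). The median log2 difference was 1.88 among the loci higher in 20G and -2.06 among those lower, and 0.02 over all tested loci. Differences of at least 4-fold on the log2(FPKM + 1) scale made up 2382 of the calls, and differences of at least 16-fold made up 334. Among all 28292 tested loci, 9733 (34.4%) had no overlap between the 3 values of one line and the 3 of the other, where chance gives 10%. Without 19G replicate 1, which stood apart from its line, 5690 loci were called, 2642 higher and 3048 lower, and 4632 of them were among the 4849.

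**Figure D2:**
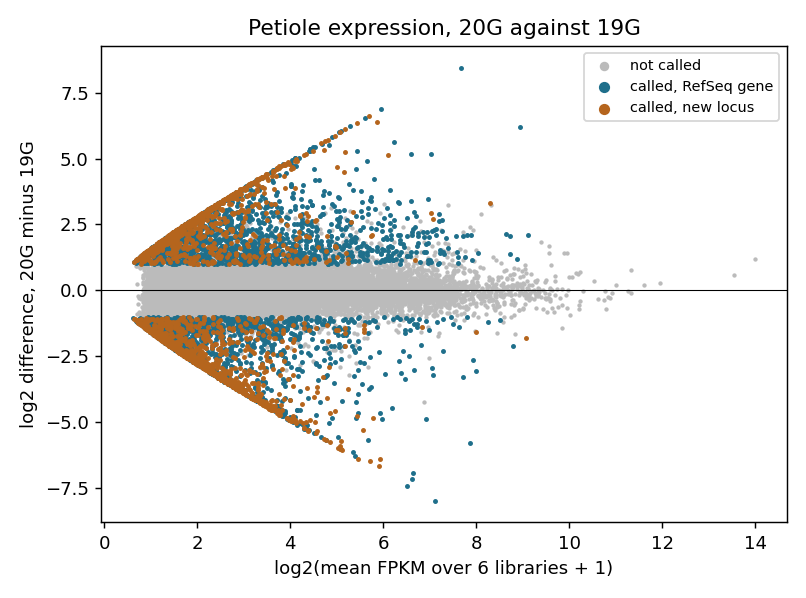
Difference between lines for each of the 28292 tested loci (y axis, log2 scale, 20G minus 19G) against mean expression (x axis, log2 of mean FPKM + 1), with called RefSeq genes, called new loci and other loci in 3 colours. Calls lie on both sides of 0 (2388 higher and 2461 lower), and many lie along the outer edges, where a locus has almost no signal in 1 line.

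Among RefSeq genes, 1424 were higher and 1249 lower in 20G. The largest increase was in LOC110928594, which averaged 406.4 ± 129.5 FPKM in 20G (SD, n = 3) and was listed at 0.0798, 0 and 0.335 FPKM in the 19G libraries. Its log2 difference was 8.45 (SE 0.26, limma adjusted p = 1.67e-05). LOC110928929 averaged 121.1 ± 30.7 FPKM in 20G (SD, n = 3) and was listed at 0, 0 and 0.0412 in 19G, a log2 difference of 6.88. LOC110930897 averaged 95.2 ± 11.7 FPKM in 20G (SD, n = 3) and did not exceed 0.0946 in 19G, a log2 difference of 6.54. LOC110890206 stood at 70.7, 98.7 and 59.1 FPKM in 20G and was listed at 0 in the 3 libraries of 19G. LOC110937343 averaged 66.5 ± 8.23 FPKM in 20G (SD, n = 3) and was listed at 0.0875, 0 and 0 in 19G. LOC110930697 was expressed in both lines, at 966.7 ± 229.2 FPKM in 20G and 15.6 ± 10.9 in 19G (SD, n = 3), a log2 difference of 6.21 (SE 0.67), or 5.37 without 19G replicate 2.

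The largest decrease was in LOC110918190, which averaged 273.6 ± 71.3 FPKM in 19G (SD, n = 3) and was listed at 0, 0.0763 and 0.131 in the 20G libraries. Its log2 difference was -7.97 (SE 0.23, limma adjusted p = 1.67e-05). LOC110922285 averaged 180.5 ± 46.9 FPKM in 19G (SD, n = 3) and did not exceed 0.0841 in 20G, a log2 difference of -7.43. LOC110879830 averaged 193.9 ± 62.3 FPKM in 19G and 0.303 ± 0.048 in 20G (SD, n = 3), a log2 difference of -7.17. LOC110940690 averaged 81.7 ± 22.3 FPKM in 19G (SD, n = 3) and did not exceed 0.113 in 20G. LOC110930696 and LOC110895162 were each listed at 0 in all 3 libraries of 20G. In 19G, LOC110895162 stood at 137.4, 64.7 and 36.0 FPKM. LOC110930696 stood at 20.4, 320.4 and 255.4 FPKM, the lowest value being that of 19G replicate 1. Its log2 difference was -6.92, and it was -8.17 without 19G replicate 1 and -6.21 without 19G replicate 2. All 12 of these genes passed the calling rule under each of the 16 alternatives to the fit. Except in LOC110930697, the size of the difference rests on the pseudocount, because one line had little or no signal: with 0.1 in place of 1, the 12 differences ran from 6.37 to 10.95 and from -8.86 to -10.71.

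**Figure D3:**
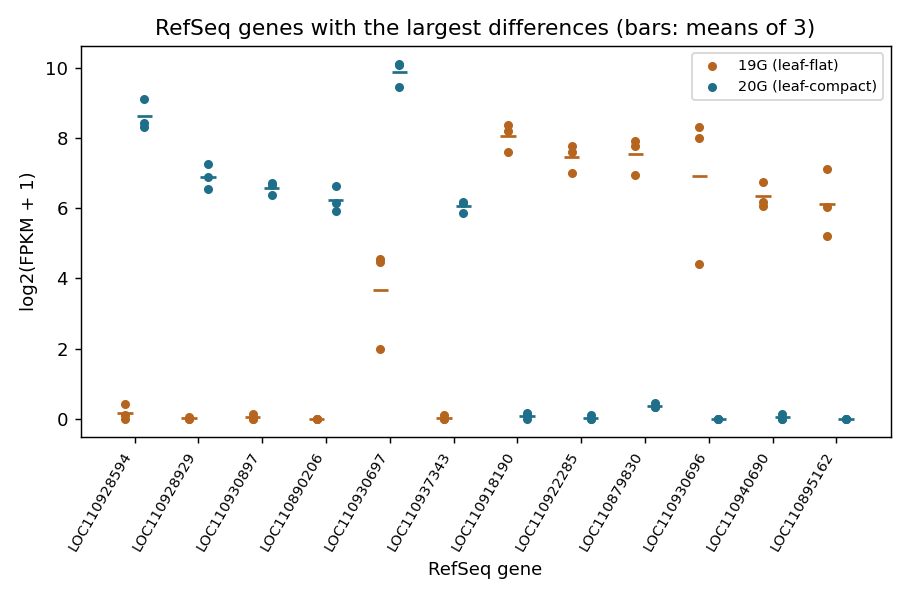
Values per library, as log2(FPKM + 1), of the 6 RefSeq genes with the largest increase (left) and the 6 with the largest decrease (right) in 20G, with a bar at the mean of each line's 3 libraries. LOC110930697 is the 1 gene of the 12 with more than trace signal in both lines, at mean FPKM of 15.6 in 19G and 966.7 in 20G.

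The most abundant transcripts were expressed in both lines. The 3 loci with the highest mean FPKM, named after their values were seen, were LOC110873772, LOC110891322 and LOC110872247, and none of them passed the test. LOC110873772 stood at 9930 ± 1965 FPKM in 19G and 22890 ± 7088 in 20G (SD, n = 3), a log2 difference of 1.18 with a 95% interval of -0.20 to 2.55 (limma adjusted p = 0.24). LOC110891322 stood at 19200 FPKM in 19G replicate 1 and at 5838 and 6118 in the other 2 libraries of that line, against 10190 to 16770 in 20G. Its log2 difference was 0.59 with a 95% interval of -0.97 to 2.15. LOC110872247 differed by 0.30 on the log2 scale, with a 95% interval of -0.59 to 1.19. The 10 most abundant loci took 9.0% of summed FPKM in 19G replicate 1 and 5.2% and 5.7% in the other 2 libraries of 19G. In 20G they took 7.3% to 9.6%.

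Part of the difference between the lines was of an on-or-off kind. At 1 FPKM or more in all 3 libraries of one line and listed at 0 in all 3 of the other were 669 loci in 20G and 855 loci in 19G. Their median level in the line that expressed them was 4.02 FPKM in 20G and 4.40 in 19G. All 1524 such loci passed the calling rule, and they made up 31.4% of the calls. Their definition alone gives a log2(FPKM + 1) difference of at least 1 and no overlap between lines. The fold part of the rule was therefore met by construction. RefSeq genes accounted for 205 of the loci of 20G and 281 of those of 19G. The remaining 1038 (68.1%) were new loci, which made up 18.1% of the loci tested. At a level of 5 FPKM or more in the expressing line, 232 loci of 20G and 249 of 19G remained. At this kind of value a 0 cannot be told from a transcript that failed to be estimated.

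New loci differed between the lines more often than RefSeq genes. Of 5130 tested new loci, 2176 (42.4%) were called, 964 higher and 1212 lower in 20G. Of 23162 tested RefSeq genes, 2673 (11.5%) were called. New loci were expressed at a lower level, with a median of 3.55 FPKM against 8.55 for RefSeq genes. RefSeq genes matched to the new loci in 20 bins of expression were called at 19.6%, still below the 42.4% of new loci (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Of the called new loci, 1038 were listed in only one line and met the fold criterion by definition, as did 205 RefSeq genes of 20G and 281 of 19G. Matching used the mean over both lines, which a lack of signal in one line lowers. The matched rate therefore depends in part on the difference itself. The highest number of called new loci in the permutations was 1460. These permutations treat each locus as independent. Called RefSeq genes lay near each other in the gene order, and several new loci may belong to one transcript. The permutations may therefore understate the spread that chance gives. The new loci were assembled by the authors, and whether these 6 libraries supplied them is not given in the sources used here.

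Called RefSeq genes lay next to each other in the gene order more often than permuted calls did, a comparison made after the data had been seen. Of 23108 ordered genes, 2662 were called. Adjacent pairs called in the same direction numbered 370, against 157.5 expected from calls permuted among genes of like expression, a ratio of 2.35 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Same-direction pairs were also in excess at 2 to 5 genes apart (ratio 1.49), at 6 to 10 genes apart (ratio 1.35) and at 11 to 50 genes apart (ratio 1.17), each at the same p. Adjacent pairs called in opposite directions numbered 165 against 156.3 expected (ratio 1.06, permutation p = 0.2). The ratio for adjacent same-direction pairs was 5.42 among the 484 called genes listed in only one line and 2.36 among the other 2178. The 2178 still include genes with only trace signal in one line. This split therefore does not show whether the excess rests on genes nearly absent from one line. Runs of at least 3 consecutive tested genes called in one direction numbered 58, holding 200 genes, against 9.0 expected and 21 at most in 2000 permutations.

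The longest runs, named after their values were seen, held mostly genes with little or no signal in one line. A run of 7 genes from LOC110877225 to LOC110877247 was lower in 20G, with log2 differences of -3.23 to -1.41. Within it LOC110877240, LOC110877237, LOC110877241 and LOC110877242 were listed at 0 in all 3 libraries of 20G and averaged 1.67 to 2.93 FPKM in 19G. Its last member, LOC110877247, had an adjusted p of 0.048 by limma and stood at 4.89 ± 3.51 FPKM in 19G and 0.793 ± 0.556 in 20G (SD, n = 3). A run of 6 genes from LOC110899232 to LOC110899257 was lower in 20G, with log2 differences of -4.46 to -2.97. LOC110899232 averaged 21.4 ± 0.99 FPKM in 19G and LOC110899257 averaged 17.6 ± 2.25 (SD, n = 3), while neither exceeded 0.0436 FPKM in 20G. A run of 6 genes from LOC110883700 to LOC110889018 was higher in 20G, with log2 differences of 1.71 to 3.40. LOC110883700 averaged 9.81 ± 3.00 FPKM in 20G (SD, n = 3) and was listed at 0 in the 3 libraries of 19G. Whether members of a run are copies of one another was not examined, so reads shared between copies leave these values uncertain.

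**Figure D4:**
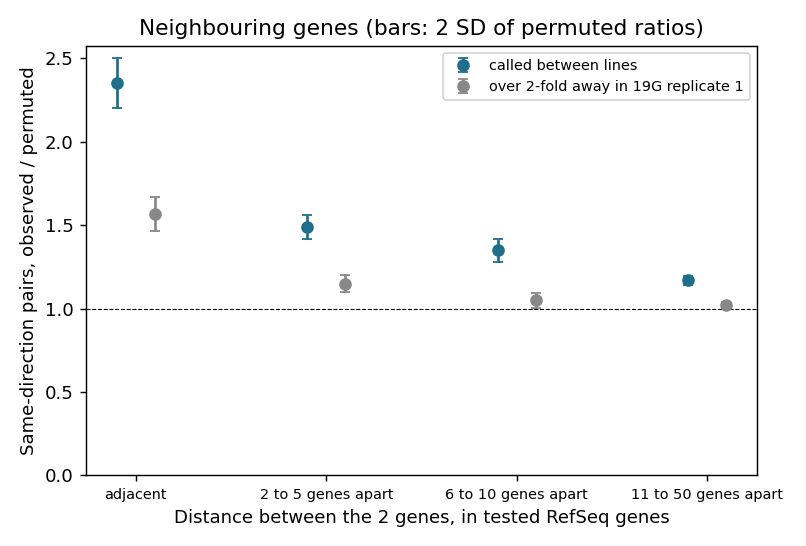
Ratio of observed to permuted same-direction pairs (y axis) by the distance between the 2 genes in tested RefSeq genes (x axis), for genes called between the lines and for genes over 2-fold away in 19G replicate 1 from the other 2 libraries of 19G. Bars are 2 SD of the permuted ratios, and the dashed line marks a ratio of 1. The 2 sets were formed by different criteria. The genes called between lines lie above the others at each distance, from 2.35 against 1.57 for adjacent genes to 1.17 against 1.02 at 11 to 50 genes apart.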

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

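The number of called loci stayed within 1.5 times the 4849 reported under every alternative but one: testing only loci with a mean FPKM of at least 5 left 1860 calls, 994 higher and 866 lower in 20G, of which 1237 were RefSeq genes and 623 new loci. That alternative tests fewer loci by its construction, and all 1860 were among the 4849. The 12 named genes kept their direction and their call in all 192 values, but not the size of the difference: with a pseudocount of 0.1, LOC110928594 moved from 8.45 to 10.95, LOC110928929 from 6.88 to 10.05 and LOC110922285 from -7.43 to -10.49. Sample weights moved LOC110930697 to 7.17 and LOC110930696 to -8.04. With each library left out in turn, calls ranged from 4345 to 5690, from 2099 to 2642 higher in 20G, from 2236 to 3048 lower, from 2242 to 3430 among RefSeq genes and from 2095 to 2260 among new loci. The highest total, 5690, was that without 19G replicate 1. The replicate numbers gave no pairing that held over all libraries: deviations of same-numbered libraries correlated at 0.24, -0.01 and 0.13. Replicate 1 of 19G and replicate 1 of 20G correlated best with each other, and 19G replicate 3 correlated best with 20G replicate 3. The remaining libraries correlated best with another number. A factor shared by the libraries numbered 1 is therefore not excluded. With the replicate number as a block 5126 loci were called, 4807 of them shared with the fit without it. Median-of-ratios scaling gave 47.4% of calls as higher in 20G, quantile normalization 49.2%, and no scaling moved the median of all loci by more than 0.1 on the log2 scale. Loci listed in only one line, under alternatives chosen after seeing the data, fell to 232 in 20G and 249 in 19G when 5 FPKM was required. They rose to 893 in 20G and 1153 in 19G when 0.5 FPKM was enough. With up to 0.1 FPKM allowed in the absent line, they rose to 826 and 1121, so the counts depend on where absence is set. They ranged from 716 to 749 in 20G and from 887 to 1045 in 19G with each library left out, which relaxes the definition. The ratio of adjacent same-direction pairs ranged from 2.00, without 19G replicate 1, to 2.59 with each library left out, and its permutation p stayed under 0.05 in the other alternatives too. The planned tests on counts and on recovered reads were not run because the files hold FPKM only, and the gene list tests, with their alternatives, were not run because no product names pair with the identifiers. Depth is unknown, so how far it limits low loci cannot be stated.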

Other observations

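The tests on 19G replicate 1 and on splits of the libraries were chosen after their results had been seen; those on neighbouring genes were written down before their results were seen, for a pattern sought after the calls were known.

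The real split of the 6 libraries by line called 4849 loci, and the highest of the other splits into 3 and 3 called 0 by limma, with 108 to 1992 loci at an unadjusted p under 0.05 in those splits. Loci listed in only one group of 3 libraries numbered 1524 in the real split and at most 2 in any other. In both counts only the real split of the 10 reached the real value, and 10 splits are too few for a share under 0.05. In the other splits each group held libraries of both lines. The difference between the lines therefore added to the spread within groups, which lowers the number of calls. A locus listed in only 1 line could not be listed in only 1 group of those splits. Their low counts are thus no baseline for chance, and no conclusion is drawn from the comparison.

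Neighbouring genes called in one direction may mark chromosome segments at which 19G and 20G carry different sequence. Segments whose genes differed in either direction would also raise the number of opposite-direction pairs. Over all called genes those pairs were not clearly in excess, at ratios of 1.06 for adjacent genes (permutation p = 0.2) and 1.02 at 6 to 10 genes apart (permutation p = 0.3). Among the 484 called genes listed in only one line, adjacent opposite-direction pairs numbered 10 against 5.8 expected (ratio 1.73, permutation p = 0.07). Among the other 2178 the ratio was 1.05 (permutation p = 0.3). An excess among genes listed in only one line is therefore not excluded. Calls arranged by chance among genes of like expression would not give the observed 370 adjacent same-direction pairs (permutation p = 0.0001). The excess 6 to 10 genes apart, at a ratio of 1.35, argues against reads shared between immediate neighbours as the whole cause. Such reads could still add to the larger excess of adjacent pairs, at a ratio of 2.35. Reads shared between copies further apart are not addressed by it. Whether neighbouring genes vary together in any petiole sample cannot be told apart from a difference of the lines: genes over 2-fold away in 19G replicate 1 were also in excess, at ratios of 1.57 for adjacent genes and 1.15 at 2 to 5 genes apart (permutation p = 0.0005 for both), 1.05 at 6 to 10 (p = 0.02) and 1.02 at 11 to 50 (p = 0.03). The lower ratios there exclude nothing, because that set comes from 1 library and from a bare fold criterion in place of a test. Sequence divergence between lines, reads lost against the reference, families of tandem copies and regulation differing between the lines over a whole segment stay open as well, since no genotype or sequence was analysed here.

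The library 19G replicate 1 stands apart from the other 2 libraries of its line at 4278 loci. A mixture with 20G material is argued against: over 260 loci listed at 0 in the other 19G libraries and at 5 FPKM or more in every 20G library, its median level was 0.00% of the 20G mean, with 232 loci at 0 and 14 above 5%. Over 364 loci of 19G listed at 0 in 20G, it held a median of 66.6% of the level in its sister libraries, with 3 loci at 0. Other values went the other way. Of the 19G libraries it lay nearest to 20G, at -74.0 on the first principal component against -101.6 and -103.4. Its r with the 20G libraries was 0.774 to 0.796, against 0.752 to 0.768 and 0.746 to 0.760. The level of 66.6% would also go with dilution, though its lower median-of-ratios factor (0.86 against 1.06 and 1.08) lowers that level too. A scale factor moved by a few abundant loci is argued against, since 4048 loci stayed over 2-fold away after median-of-ratios scaling, against at most 1969 in any other library. Differences in petiole age, position, time of sampling or RNA handling stay open; no label separates the replicates and no biological explanation was tested.

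The 2 genes LOC110930697 and LOC110930696, adjacent among tested genes, changed in opposite directions, by 6.21 and -6.92 on the log2 scale (5.37 and -6.21 without 19G replicate 2, 6.65 and -8.17 without 19G replicate 1), and their summed FPKM averaged 966.7 in 20G and 214.3 in 19G. A candidate explanation for such pairs is that near-identical neighbours divide the same reads differently in the 2 lines, which would leave their sum nearly equal. Over the 165 opposite-direction adjacent pairs the median size of the log2 difference of sums was 0.85. In 10000 random sets of like expression the median was 0.84 and the 5th percentile 0.76. As a set, the adjacent pairs thus had sums no nearer to equal than random pairs. This does not exclude divided reads. Permuted calls gave 156.3 such pairs, so most of the 165 may be neighbours by chance and would hide a minority with divided reads. FPKM is also scaled to length, so divided reads need not keep the sum equal. Single pairs stay open as well. LOC110873555 and LOC110873554, named after their values were seen, changed by 4.79 and -2.20 and left a difference of sums of 0.08.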
